A study of Mus musculus with 128 samples.

How the data were processed

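The study measured RNA in interscapular brown (BAT) and reproductive white adipose tissue (WAT) of SM/J and LG/J mice on 2 diets, at 20 and 30 weeks, in both sexes, with 4 libraries in each of 32 groups and 128 libraries in all. Per the labels, the tissue was frozen, RNA was taken with a kit for lipid-rich tissue, and libraries were made from total RNA after removal of ribosomal RNA. Per the submitters' processing notes, reads were aligned with STAR 2.6.0c to the mm10 mouse genome and handled with edgeR, for which no version is stated.

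The deposited values are a signal per gene and library, read here as normalised counts that the authors scaled within each table to 1 common library size. The values are fractional and never negative, library totals ran from 16293526 to 21799085, and library medians within a table differed by 0.0549 to 0.168 on the log2 scale. Low values of 112 of the 128 libraries lay near evenly spaced steps of 0.836 to 1.178, and in the 13 libraries where the values kept closest to them (clarity over 0.99) the steps were 0.984 to 1.014, so whole reads were not recovered and the depth in reads is unknown. Each of the 8 tables (1 strain, diet and tissue, 16 libraries) was filtered and scaled by itself and held 12716 to 14110 genes, with a lowest mean per gene of 15.2 to 18.6 and at most 0.017% of values at 0. The SM/J high-fat BAT table was unlike the others. Its genes stood nearly in the order of their age p (Spearman correlation 0.969), and its values had 2 decimals where the others had up to 9. The SM/J low-fat WAT and LG/J low-fat WAT tables were also not sorted by gene identifier, with correlations of 0.383 and 0.0322. All tables were analysed in the same way, and the reason for the differences is unknown. Between 112 and 148 identifiers per table matched no symbol in the GENCODE M21 annotation, which also gave the positions. Genes of the X and Y chromosomes and of the mitochondrial genome are not analysed here.

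Because the values are not whole counts, the test was the fallback fixed for that case, limma-trend (limma 3.58.1 in R 4.3.3) on log2 of the value plus a pseudocount of 1, two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all genes of the comparison. The comparisons, the gene lists, the rule for naming genes and the alternatives of the processing were chosen before the data were examined, except where the text says otherwise. Age was tested within each table with sex as covariate, and sex within each table with age as covariate. Differences of age effects between diets, strains and sexes were tested as interactions of group means, in which a scale factor per table cancels. Age by tissue in SM/J mice on the high-fat diet, sex by diet in SM/J BAT, and sex in 6 further tables were added after the data were seen. For age by tissue the animal was a block, since the replicate numbers recur in both tissues. Over the genes of both tables, the 16 BAT libraries of SM/J mice on the high-fat diet correlated with the WAT library of the same number at a median of 0.202 after removal of group means. Other numbers of the same age and sex gave a median of -0.0716. Removing group means makes these negative where the own correlations are positive, so they add no separate support. Among the 4 WAT libraries of their own age and sex, where 1 in 4 would match by chance, 13 of the 16 correlated best with their own number. In SM/J low-fat, LG/J high-fat and LG/J low-fat mice 12, 10 and 9 of 16 did, with medians of 0.191, 0.123 and 0.132 and a lowest of -0.269 in LG/J low-fat mice, so the number was taken as the animal with less support there. Comparisons of diet, strain or tissue across tables had been planned as tests, and no test is given. A difference between separately scaled tables also holds their scaling, and a small one cannot be told from it.

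Of 28 fixed lists of genes for adipocyte functions and for markers of cell types that the depots could hold, those with at least 3 measured genes were tested. Each list was tested by camera with a preset correlation of 0.01, by camera with a correlation estimated from the libraries, and by fry, each adjusted over the lists of a comparison. The result of 1 list and 1 gene in it is not reported here. Camera compares a list with other genes, and fry tests whether its genes move on balance one way, or in either direction. Members past the threshold were counted over all genes and adjusted over the list alone. The genes named are, for the age effect in SM/J BAT and WAT on the high-fat diet, up to 10 largest rises and 10 largest falls with an adjusted p under 0.05, a mean of at least 5 per 1000000 normalised counts (CPM), the same sign in both sexes and a symbol that is not a predicted or clone name. For other comparisons they are up to 4 rises and 4 falls, and for each list the 4 members with the smallest p. Ucp1, Lep, Adipoq, Cidea, Fasn, Col1a1, Adgre1 and Mki67 were always followed.

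The same code was tested on simulated data with 200 changed genes in the layout of each comparison. The simulated noise was independent between genes and libraries. Genes of the real libraries move together, so recovery and false calls there may be worse than these figures. For age in SM/J high-fat BAT it recovered 80.6%, 98.5% and 100% of changes of 1.5, 2 and 4-fold with 5 false calls, and in SM/J high-fat WAT 82.1%, 94% and 98.5% with 9 false calls. Recovery of 1.5-fold changes was lower in differences of effects, at 59.7% and 47.8% for age by diet in BAT and WAT, 52.2% and 53.7% for age by strain, and 29.9% and 28.4% for sex by age (55.2% and 67.2% of 2-fold changes). Alternatives were a pseudocount of 0.1, rescaling by the median of ratios (RLE), only genes with a mean of at least 5 CPM, 1 fit to all 64 libraries of a tissue, each sex alone, each library left out in turn, and an estimated camera correlation. Alternatives chosen after seeing the data were marker scores as covariates, leaving out libraries with muscle transcripts or with doubtful identity, and no block by animal. For 100 splits of the libraries, the real one and 99 drawn with seed 20, called genes were counted with age shuffled within table and sex, or sex within age.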

Results

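RNA was sequenced from interscapular brown adipose tissue (BAT), the heat-producing depot between the shoulder blades, and from reproductive white adipose tissue (WAT), a lipid-storing depot, of mice of the inbred strains SM/J and LG/J. The mice ate a high-fat or a low-fat diet and were 20 or 30 weeks old. With 2 sexes and 2 tissues this made 32 groups of 4 libraries, or 128 libraries, taken as 64 animals because the replicate numbers recur in both tissues. Each of the 8 tables held the 16 libraries of 1 strain, diet and tissue, with 12716 to 14110 genes per table. Library totals ran from 16293526 to 21799085 normalised counts, and libraries of a group correlated at Pearson's r of 0.926 to 0.992 across genes, which are not independent replicates. Levels below are normalised counts with their SD, and changes are on the log2 scale with their standard error (SE).

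The central question was what differs in the brown fat of obese SM/J mice between 20 and 30 weeks, the ages that the series sets on either side of a remission of disturbed glucose control. In SM/J BAT on the high-fat diet, 98 genes rose and 95 fell with age among 13252 tested. Among the largest rises, Cdsn, which encodes the adhesion protein corneodesmosin, went from 387 ± 93.1 to 849 ± 166 (SD, n = 8 at each age), a change of 1.14 (SE 0.15, adjusted p = 0.00219). Alas1, the first enzyme of haem synthesis, rose from 5162 ± 1331 to 9143 ± 1772 (change 0.85, SE 0.15, adjusted p = 0.0149). Nnat, an imprinted gene for a small membrane protein, rose from 804 ± 259 to 1686 ± 619 (change 1.05, SE 0.23, adjusted p = 0.0333). Cxcr4, the receptor for the chemokine Cxcl12, rose from 149 ± 22.3 to 248 ± 27.5 (change 0.74, SE 0.10, adjusted p = 0.00267). The other large rises were Slc15a2, a peptide transporter (1.11), Ehd3, a protein of endocytic recycling (0.94), Proser2 (0.84), Sctr, the secretin receptor (0.74), and Lvrn, an aminopeptidase (0.74). Cyp2b10, a cytochrome P450 of drug and steroid metabolism, rose by 1.58 (SE 0.32, adjusted p = 0.0241), a value that is uncertain because closely similar genes share reads. All 8 libraries at 30 weeks lay above the 20-week median for 9 of these 10 genes, and 7 of 8 did for Nnat. The genes were chosen for their rise in these same libraries, so these counts are no separate support.

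The largest falls included the alarmin cytokine Il33, which went from 422 ± 342 to 104 ± 71.2 (SD, n = 8 at each age), a change of -1.82 (SE 0.29, adjusted p = 0.00841). Il1rl1, the receptor chain that binds the Il33 protein, fell by 1.06 (SE 0.25, adjusted p = 0.0433), and Il1rn, the interleukin 1 receptor antagonist, fell by 1.38 (SE 0.32, adjusted p = 0.0388). Spp1, the secreted matrix protein osteopontin, went from 143 ± 49.6 to 58.1 ± 8.83 with an adjusted p of 0.00136. Pdpn, a membrane glycoprotein, went from 143 ± 80.1 to 61.3 ± 33.5 (adjusted p = 0.0283). Dhrs9, a retinol dehydrogenase, fell by 1.05, Prg4, a lubricating proteoglycan, by 1.03, Igf2bp2, an RNA-binding protein, by 1.11, and Mthfd1l, a mitochondrial enzyme of folate metabolism, by 0.86. Acot1, an acyl-CoA thioesterase, fell by 1.26, which is uncertain because its neighbour Acot2 is nearly identical. All 8 libraries at 30 weeks lay below the 20-week median for 9 of these 10 genes, and 7 of 8 did for Prg4, which again follows from how the genes were chosen. The uncoupling protein gene Ucp1, at 93302 ± 7130 and 82959 ± 19720, did not pass the test (change -0.20, SE 0.12, adjusted p = 0.405). The leptin gene Lep, at 9420 ± 3877 and 17998 ± 7020, did not pass either (change 0.95, SE 0.26, adjusted p = 0.0694).

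In the mm10 build with GENCODE M21 genes, Cdsn (ENSMUSG00000039518) lies on chromosome 17 from 35552128 to 35557180, and Alas1 (ENSMUSG00000032786) on chromosome 9 from 106233455 to 106248654. Il33 (ENSMUSG00000024810) lies on chromosome 19 from 29925114 to 29960718. Spp1 (ENSMUSG00000029304) lies on chromosome 5 from 104435118 to 104441050, and Cxcr4 (ENSMUSG00000045382) on chromosome 1 from 128588199 to 128592293. The 193 genes rest on both sexes together, since 3 genes passed in females alone and 1 in males alone, and 8 passed with the macrophage marker score as covariate, where all 193 kept their sign and the median change was 0.411 instead of 0.479. The count was 121 without the 20-week female 864, 64 without male 290 or male 704, and 609 without male 734, all of 20 weeks. Among the 30-week libraries it was 83, 122 and 119 without female 729, 740 and 786, and 85, 74 and 95 without male 653, 655 and 656.

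Most measured inflammatory cytokines and macrophage markers in the same tissue had lower levels at 30 weeks, and neither list was called with an estimated correlation. Of 15 measured inflammatory cytokines and chemokines, 14 had negative changes, with a median of -0.99, and Il1rn was the 1 that passed over all genes. Adjusted over the list alone, 7 passed, all lower, and Ccl2, which attracts monocytes, lay at 945 ± 796 and 393 ± 344 (adjusted p = 0.130). The camera test, which ranks a list against other genes, called this list (adjusted p = 7.97e-05), but its adjusted p was 0.676 with an estimated correlation. Of 21 macrophage markers 17 were lower, and Itgam (451 ± 121 to 304 ± 56.5) and Mmp12 (396 ± 109 to 253 ± 55.9) fell. Adjusted over the list alone, 8 macrophage markers were lower and 2 higher, so that the markers did not move as 1 block (camera adjusted p = 0.014, and adjusted p = 0.676 with an estimated correlation). Fry's test for change in either direction gave them an adjusted p of 0.000656. Collagens and other matrix genes were lower in 26 of 28 cases with a median of -0.17 and none past the threshold, as for Col3a1 at 17510 ± 4101 and 13334 ± 3361 (camera adjusted p = 0.000281, and adjusted p = 0.676 with an estimated correlation). Of 10 preadipocyte and fibroblast markers 8 were lower, and Ly6a fell from 2699 ± 785 to 1741 ± 242 (camera adjusted p = 0.0337, and adjusted p = 0.676 with an estimated correlation).

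White adipocyte genes were higher in 12 of 15 cases, with Nnat called over all genes and 4 adjusted over the list alone (camera adjusted p = 0.0163, and adjusted p = 0.676 with an estimated correlation). Cell cycle genes were lower in 15 of 20 cases, with none past the threshold either way (camera adjusted p = 0.0371, and adjusted p = 0.701 with an estimated correlation). All 13 skeletal muscle markers were lower with a median of -1.79 and none passed, as for Tnni2 at 778 ± 917 and 615 ± 1051 (camera adjusted p = 0.0337, and adjusted p = 0.842 with an estimated correlation). Brown and thermogenic adipocyte genes showed no common direction, with 9 higher, 10 lower and 0 of 19 past the threshold. The respiratory chain (35 genes), fatty acid synthesis (15), insulin signalling (18), glycolysis and glucose uptake (16), interferon response (16), unfolded protein response (14) and circadian clock (13) also had 0 members past the threshold and no camera call. Of the lists with some members past it when adjusted over the list alone, lipid droplet genes had 3 higher and 2 lower of 21, with Plin2, a droplet coat protein, at 41465 ± 11022 and 27831 ± 4964. Fatty acid oxidation had 1 lower of 19, brown adipose secreted factors 2 lower of 12, and immediate early genes 1 lower of 13. Endothelial (12), B cell (3), T and NK cell (2), mesothelial (1), ovary and oviduct (2) and red blood cell (3) markers had none. Of the 23 lists of at least 3 measured genes, 7 were called by camera and 0 with an estimated correlation.

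On the low-fat diet, the control for obesity, no gene of SM/J BAT passed the test with age. All 13 skeletal muscle markers had lower levels at 30 weeks, with a median of -3.77, and the list was not called with an estimated correlation. The fast myosin gene Myh1 lay at 1108 ± 966 and 155 ± 318 (SD, n = 8 at each age), a change of -4.86 (SE 1.12, adjusted p = 0.132), and the calsequestrin gene Casq1 at 84.6 ± 68.1 and 17.2 ± 20.2 (change -2.34, SE 0.45, adjusted p = 0.132). In both genes all 8 libraries of 30 weeks lay below the 20-week median. Adjusted over the list alone all 13 passed (camera adjusted p = 1.2e-14, and adjusted p = 0.518 with an estimated correlation). Respiratory chain genes were higher in 27 of 35 cases, matrix genes in 24 of 28 and macrophage markers in 18 of 21, and all 3 camera calls were lost (adjusted p = 0.82 with an estimated correlation for each). Limma called 0 of 12875 genes, with 1879 at an unadjusted p under 0.05. The count was 258 without the 20-week male 650, 49 without male 336, 5 without male 542 and 1 without the female 699 of that age.

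**Figure D1:**
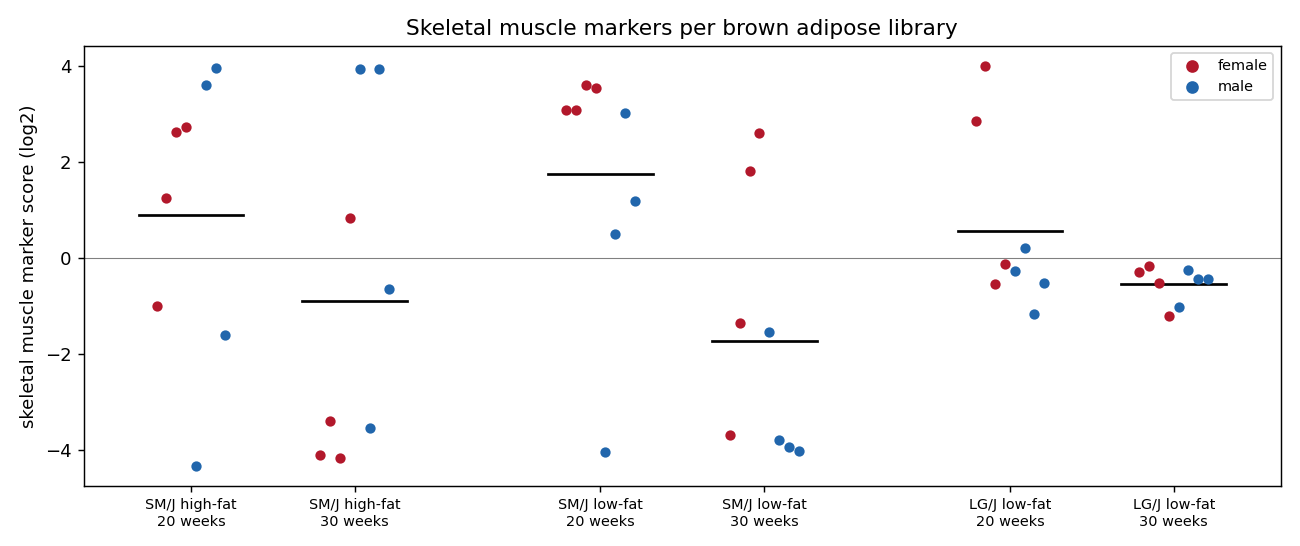
Skeletal muscle marker score of each BAT library, the mean log2 level of the measured markers centred within its table, for the 3 tables with enough markers, with 1 point per library and bars at group means. In SM/J on the low-fat diet the mean score at 30 weeks minus that at 20 weeks was -3.49.

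Whether the age effect of SM/J BAT differed between the diets was tested directly, and 0 of 12759 genes passed in limma, with 1212 at an unadjusted p under 0.05. Matrix genes had negative differences in 27 of 28 cases, inflammatory cytokines in 14 of 14 with a median of -1.23, and macrophage markers in 19 of 21 (adjusted p = 0.618 with an estimated correlation for each). Skeletal muscle markers differed the other way, with 13 of 13 positive and a median of 1.52 (adjusted p = 0.837 with an estimated correlation). The count rose from 0 to 1 without female 862 or male 734 of 20 weeks or male 655 of 30 weeks, all on the high-fat diet.

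LG/J mice, the comparison strain, showed no called gene with age in BAT on either diet. On the high-fat diet Ucp1 had a change of 0.00 (SE 0.14) and Lep, at 3483 ± 2405 and 3602 ± 2958, one of -0.17 (SE 0.55, adjusted p = 0.984, n = 8 at each age). Limma called 0 of 12716 genes (539 at an unadjusted p under 0.05) on the high-fat diet and 0 of 12904 (592) on the low-fat diet. Immediate early genes, which respond first to stimuli, were higher in 13 of 13 cases on the high-fat diet (median 0.37), and respiratory chain genes lower in 35 of 35 with a median of -0.10 (adjusted p = 0.83 with an estimated correlation for both). On the low-fat diet red blood cell genes were higher in 4 of 4 cases, with a median of 0.79 (camera adjusted p = 0.033, and adjusted p = 0.779 with an estimated correlation). In the direct test of the age effects on the high-fat diet between the strains, 3 genes differed in BAT. Dut, which removes dUTP, lay at 275 ± 21.3 and 372 ± 27.4 in SM/J and at 296 ± 27.1 and 272 ± 30.2 in LG/J (difference 0.56, SE 0.10, adjusted p = 0.0359, n = 8 in each group). Tctn1, a gene of the primary cilium (0.75), and Gldc, which cleaves glycine (-1.27), also passed, and both lie outside the rule for naming genes and were chosen after their values were seen. Respiratory chain genes had positive differences in 35 of 35 cases (adjusted p = 0.894 with an estimated correlation). Splits of the libraries gave as many genes often enough that chance was not excluded, and leaving out 1 library gave 0 to 22 genes, with 0 without 22 of the 32 libraries and 22 without the SM/J male 734 of 20 weeks, while 1 fit to all 64 BAT libraries gave 0.

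The 193 age genes of SM/J BAT on the high-fat diet were followed in the other tables. In SM/J BAT on the low-fat diet 160 of 189 measured genes, or 84.7%, had the same sign, and a fry test over them gave an adjusted p of 0.152 over the 7 tables compared. In SM/J high-fat WAT, whose libraries share their replicate numbers with the BAT libraries the genes were called in and are not independent of them, 142 of 187 had the same sign (adjusted p = 0.102). In LG/J the counts were 112 of 180 in high-fat BAT, 130 of 181 in low-fat BAT, 98 of 184 in high-fat WAT and 133 of 184 in low-fat WAT. SM/J low-fat WAT had 129 of 187. The median change of these genes in their own direction was 0.13 in SM/J low-fat BAT, against 0.47 in the table they were called in. The latter is raised by the choice of genes past the threshold there, so these values do not compare the age effects of the diets.

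**Figure D2:**
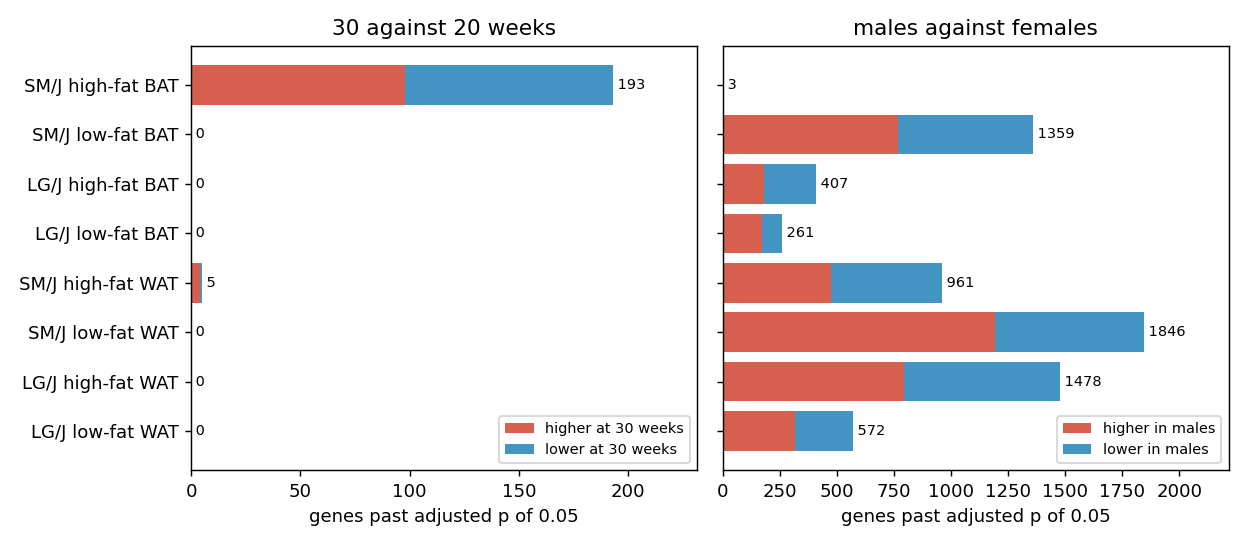
Number of genes with an adjusted p under 0.05 in each of the 8 tables for age and for sex, as bars from 0. For age the bars stand at 193 in SM/J high-fat BAT and 5 in SM/J high-fat WAT and at 0 elsewhere.

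In the reproductive white fat of SM/J mice on the high-fat diet, the depot set beside the brown fat, 4 genes rose and 1 fell with age among 13985. Tlcd2, a membrane protein gene on chromosome 11 from 75461715 to 75470899, went from 1845 ± 306 to 1234 ± 152 (SD, n = 8 at each age), a change of -0.57 (SE 0.09, adjusted p = 0.0404), and lay below the 20-week median in 8 of 8 libraries. Gldc rose by 0.67 (SE 0.11, adjusted p = 0.0404). The predicted genes Gm7592 (0.93, adjusted p = 0.00427), Gm2619 (1.33, adjusted p = 0.0404) and Gm7609 (0.78) also rose, and their values are uncertain because such gene models may share reads. These 4 lie outside the rule for naming genes and were chosen after their values were seen. Lep, at 88750 ± 11546 and 89912 ± 16785, and Ucp1, at 746 ± 758 and 526 ± 302, did not pass. The count was 1 in males alone and 0 in females alone in limma, where 424 genes had an unadjusted p under 0.05. It was 9 without the 20-week female 864, 3 without female 862, 2 without the 30-week male 700, and 1 without female 756 or male 290, 703, 704 or 734 of 20 weeks or female 646, 740 or 786 or male 653, 655 or 656 of 30 weeks.

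Cell division genes in this depot were lower at 30 weeks in 19 of 20 cases, with a median of -0.20. Adjusted over the list alone 10 passed, while 0 did over all genes. Top2a, which untangles DNA in dividing cells, lay at 1294 ± 230 and 981 ± 221 (n = 8 at each age, change -0.41, SE 0.07, adjusted p = 0.0579). The list had an adjusted p of 0.008 by fry, 1.03e-11 by camera, and an adjusted p = 0.0859 with an estimated correlation. Macrophage markers were lower in 20 of 21 cases, as for the scavenger receptor Msr1 at 2017 ± 224 and 1592 ± 293 (camera adjusted p = 5.63e-07, and adjusted p = 0.543 with an estimated correlation). Interferon response genes were lower in 16 of 16 (adjusted p = 0.517 with an estimated correlation), and fatty acid synthesis genes in 12 of 15 (adjusted p = 0.74 with an estimated correlation). Adjusted over the list alone, 1, 1 and 2 genes of these 3 lists passed, all lower. The B cell markers went the other way in 5 of 6 cases without a call. In this depot skeletal muscle markers were measured for 4 genes and the median lay at 0.03.

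On the low-fat diet most genes of brown-type adipocytes had higher levels in SM/J WAT at 30 weeks, with no single gene past the test. Of 17 brown and thermogenic genes 15 were higher, with a median of 0.92, and 9 passed adjusted over the list alone (camera adjusted p = 7.86e-10, and adjusted p = 0.218 with an estimated correlation). Ucp1 lay at 277 ± 387 and 1945 ± 2526 (SD, n = 8 at each age, change 2.65, SE 0.62, adjusted p = 0.353) and the proton channel gene Otop1 at 149 ± 118 and 565 ± 437 (change 1.83, SE 0.41, adjusted p = 0.329), and in both all 8 libraries of 30 weeks lay above the 20-week median. Respiratory chain genes were higher in 35 of 35 cases (median 0.30), fatty acid oxidation in 18 of 18 (median 0.36) and glycolysis in 16 of 16, with adjusted p = 0.607, adjusted p = 0.446 and adjusted p = 0.446 with an estimated correlation. Mesothelial markers, of the tissue's outer lining, were lower in 8 of 8 cases with a median of -0.71 (adjusted p = 0.446 with an estimated correlation). Preadipocyte markers were lower in 8 of 9 (adjusted p = 0.218 with an estimated correlation). Limma called 0 of 13967 genes, with 1338 at an unadjusted p under 0.05. Tested directly between the diets, 0 of 13715 genes differed (869 at an unadjusted p under 0.05). Of the thermogenic genes 14 of 16 had negative differences there, as for Otop1 (-1.89, SE 0.37, adjusted p = 0.25), and the list's camera call was lost (adjusted p = 0.539 with an estimated correlation).

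LG/J WAT had 0 called genes with age on the high-fat diet (435 of 13909 at an unadjusted p under 0.05) and on the low-fat diet (887 of 14110) in limma. On the high-fat diet interferon response genes were lower in 16 of 16 cases with a median of -0.20, and immediate early genes higher in 13 of 13 with a median of 0.32 (adjusted p = 0.263 with an estimated correlation for both). Ifit1, an interferon-induced antiviral gene, lay at 153 ± 39.3 and 108 ± 31.3 (n = 8 at each age), and no library of 30 weeks lay above the 20-week median. On the low-fat diet respiratory chain genes were higher in 35 of 35 cases and macrophage markers lower in 21 of 21 with a median of -0.56 (adjusted p = 0.574 and adjusted p = 0.593 with an estimated correlation). Cd68, a macrophage lysosome protein, lay there at 2773 ± 1994 and 1759 ± 1983. Between the strains on the high-fat diet 0 of 13519 genes differed in their age effect in WAT (354 at an unadjusted p under 0.05 in limma). B cell markers had positive differences in 5 of 5 cases, with a median of 0.86 (camera adjusted p = 0.000533, and adjusted p = 0.396 with an estimated correlation).

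A comparison added after the data were seen asked whether age acted differently in the brown and white fat of SM/J mice on the high-fat diet, with libraries paired by replicate number. It called 11 genes among 12820, 1 with a more positive change in BAT and 10 with a more negative one. Cxcr4 rose in BAT and lay at 647 ± 142 and 654 ± 69.6 in WAT (difference 0.71, SE 0.12, adjusted p = 0.0299, n = 8 in each group). Slc4a4, a sodium bicarbonate transporter, went from 8336 ± 977 to 5278 ± 990 in BAT and lay at 954 ± 141 and 1142 ± 208 in WAT (difference -0.93, SE 0.14, adjusted p = 0.0227). Thbd, the anticoagulant receptor thrombomodulin, had a difference of -0.84 and Sema3f, a secreted guidance protein, one of -1.20. The others were Gldc (-1.17), Epb41l3 (-0.63), Zfp36l2 (-0.63), Hip1r (-0.54), Mark4 (-0.52), Unc119b (-0.45) and Cdv3 (-0.39), of which those outside the rule for naming genes were chosen after their values were seen. Inflammatory cytokines had negative differences in 14 of 14 cases, with 5 past the threshold adjusted over the list alone (camera adjusted p = 0.00196, and adjusted p = 0.966 with an estimated correlation). Leaving out 1 animal gave 1 to 264 genes, with 1 without 756, 2 without 656, 4 without 655, 5 without 290, 6 without 292, 20 without 653, 24 without 700, 88 without 734 and 264 without 862, and 4 passed when the pairing was left out.

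Sex was compared within each table, and in WAT of SM/J mice on the high-fat diet 472 genes were higher and 489 lower in males among 13985, a count of 961 that was 262 in 1 fit to all 64 WAT libraries. The reproductive depot lies by different organs in females and males. In every WAT comparison of the sexes, a difference of sex therefore cannot be told from one of depot site. Sult1e1, the estrogen sulfotransferase, lay at 0.628 ± 0.987 in females and 548 ± 366 in males (SD, n = 8 in each sex, change 8.27, SE 0.40, adjusted p = 5.91e-10). The complement gene C7 lay at 72.9 ± 32.3 and 1046 ± 568 (change 3.76, SE 0.29, adjusted p = 1.78e-07). Mmrn1, a gene of platelets and lymphatic vessels, and Ccl21a, a lymphatic chemokine, were higher by 3.69 and 4.91, the latter uncertain because the mouse genome holds several copies. Lower in males were Cntn1, an adhesion molecule (-8.21), the complement gene Hc (-3.16), and the positional transcription factors Hoxa10, at 290 ± 35.6 and 12.3 ± 10.4, and Hoxa9 (-4.00). Sult1e1 lies on chromosome 5 from 87575969 to 87591594, C7 on chromosome 15 from 4988762 to 5063740, and Hoxa10 on chromosome 6 from 52231197 to 52240854. Adiponectin (Adipoq) was higher in males, at 23782 ± 2524 and 32382 ± 4130 (adjusted p = 0.00406).

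Interferon response genes were lower in males of this table in 16 of 16 cases, 13 of them past the threshold over all genes and 15 adjusted over the list alone, with a median of -0.53. This call held with an estimated correlation (adjusted p = 0.0264), though sex and depot site cannot be told apart here. Ifi44 lay at 337 ± 61.9 in females and 153 ± 42.3 in males and Oas1a, which senses viral RNA, at 381 ± 38.9 and 226 ± 42.3 (n = 8 in each sex). Cell cycle genes were lower in 20 of 20 cases, 8 past the threshold and 13 adjusted over the list alone (adjusted p = 0.0682 with an estimated correlation). T and NK cell markers were lower in 10 of 10, with 5 past the threshold and 7 adjusted over the list alone, among them the cytotoxic genes Prf1 (-0.95) and Gzma (-1.08) (adjusted p = 0.228 with an estimated correlation). Macrophage markers had 4 members lower either way, including Mrc1 and Adgre1 (adjusted p = 0.71 with an estimated correlation), and immediate early genes 4 higher, or 6 adjusted over the list alone (adjusted p = 0.49 with an estimated correlation). White adipocyte genes went both ways, with 5 higher and 1 lower. Mesothelial markers were higher in males in 8 of 8 cases with a median of 0.75 and none past the threshold. For the difference between the sexes in the age effect limma called 0 genes in BAT (1114 at an unadjusted p under 0.05) and 0 in WAT (677), and leaving out 1 library gave 0 to 4 in BAT, with 4 without male 734, 2 without male 700 and 1 without female 740. In simulated data this comparison recovered 29.9% and 28.4% of 1.5-fold changes in BAT and WAT, so the 0 counts do not show that the sexes aged alike.

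In SM/J BAT on the high-fat diet the sexes differed in 3 genes. Apod, a lipid-binding apolipoprotein, lay at 303 ± 66.2 in females and 547 ± 133 in males (SD, n = 8 in each sex, change 0.84, SE 0.14, adjusted p = 0.0422). C7 was higher in males (1.85, SE 0.28, adjusted p = 0.0228) and Gdf3, a growth factor of the TGF beta family, lower (-1.83, SE 0.22, adjusted p = 0.00283), both chosen after their values were seen since they lie outside the rule for naming genes. Immediate early genes were higher in males in 13 of 13 cases with a median of 0.74, 9 of them past the threshold adjusted over the list alone. Inflammatory cytokines were higher in 12 of 15, with 8 past it, as for Ccl2 at 303 ± 189 and 1036 ± 764 (adjusted p = 0.484 with an estimated correlation for both lists). All 13 muscle markers were higher in males with a median of 1.42 (adjusted p = 0.796 with an estimated correlation). Splits of the libraries gave as many genes often enough that chance was not excluded. The count was 305 without the 30-week male 700, 293 without the 20-week male 734 and 7 without the 30-week female 646, and 1 without female 862, 864, 729 or 740 or male 653 or 656.

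The same comparison was added for the 6 other tables after the data were seen. In SM/J BAT on the low-fat diet 766 genes were higher and 593 lower in males, with 19 of 28 matrix genes past the threshold and higher (23 adjusted over the list alone, median 0.64, and adjusted p = 0.227 with an estimated correlation). Thbs1, a matrix glycoprotein, lay there at 747 ± 743 and 2954 ± 2067, and the muscle myosin Myh1 at 1149 ± 950 and 113 ± 194 (n = 8 in each sex), so muscle markers moved with sex too, 8 of 13 lower in males past the threshold (adjusted p = 0.257 with an estimated correlation), and 369 genes passed with the muscle score as covariate. Leaving out 1 library gave 532 to 1836 genes there, with 598 and 532 without the 20-week females 724 and 730, 891 and 839 without males 336 and 542 of that age, and 749 and 837 without the 30-week female 489 and male 552. Of the immediate early genes 11 of 13 were higher (adjusted p = 0.227 with an estimated correlation). In WAT of the same mice 1191 genes were higher and 655 lower, and 18 of 21 macrophage markers were higher with a median of 1.61, as for Gpnmb, a gene of lipid-laden macrophages, at 2059 ± 971 and 17714 ± 12851 (adjusted p = 0.403 with an estimated correlation). Without the 20-week female 699 the WAT count of 1846 was 2860. The difference between the diets in the sex effect in SM/J BAT was tested and called 2 genes, Mrc2, a receptor for collagen uptake (-0.77, SE 0.13, adjusted p = 0.033), and Sypl2, a protein of muscle membranes (1.36, SE 0.24), the latter chosen after its value was seen. There, matrix genes had negative differences in 27 of 28 cases (17 adjusted over the list alone, adjusted p = 0.0671 with an estimated correlation), as had macrophage markers in 21 of 21 (median -0.65, 14 adjusted over the list alone) and preadipocyte markers in 9 of 10 (adjusted p = 0.0671 with an estimated correlation for both), and skeletal muscle markers had positive ones in 13 of 13, with a median of 5.01 (adjusted p = 0.167 with an estimated correlation). Those 2 genes became 0 in most leave-one-out fits and 30 without the low-fat female 761 of 20 weeks.

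In LG/J BAT 182 genes were higher and 225 lower in males on the high-fat diet, and 173 and 88 on the low-fat diet. Pkia, an inhibitor of protein kinase A, was higher in both, at 211 ± 90.7 and 676 ± 293 and at 171 ± 71 and 515 ± 237 (SD, n = 8 in each sex), and Slc7a10, an amino acid transporter, lower in both, with changes of -1.46 and -1.34. In WAT 796 were higher and 682 lower on the high-fat diet, and 316 and 256 on the low-fat diet. Hoxa10 was lower in males in both, with changes of -6.73 (SE 0.94, adjusted p = 0.00291) and -4.15 (SE 0.90, adjusted p = 0.0182), both fitted with the libraries 351 and 350 described below under their labels and larger in size without them. Of 16 white adipocyte genes 7 and 3 were lower past the threshold (9 and 10 adjusted over the list alone), with adjusted p = 0.592 and adjusted p = 0.538 with an estimated correlation. A WAT library labelled high-fat male (351) had C7 at 50.5 and Hoxa10 at 422, where the other 7 males lay at 540 to 929 for C7 and at most 1.94 for Hoxa10. A WAT library labelled low-fat female (350) had C7 at 849.5 and Hoxa10 at 1.45, where the other 7 females lay at 21.3 to 59 and 227 to 403. Mesothelial markers were lower in males in 8 of 8 cases on the high-fat diet, with a median of -1.33 (adjusted p = 0.592 with an estimated correlation). Leaving out 1 library gave 627 to 3562 genes for the high-fat WAT count of 1478, with 3562 without male 351, 3372 without male 537, 629, 664, 627, 691 and 774 without males 344, 403, 533, 619 and 625, and 856, 772 and 777 without females 281, 509 and 510, and 32 passed with the mesothelial score as covariate, and when 1 library was left out the low-fat WAT count of 572 was 305 to 693 and the BAT counts 176 to 700 and 72 to 811.

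**Figure D3:**
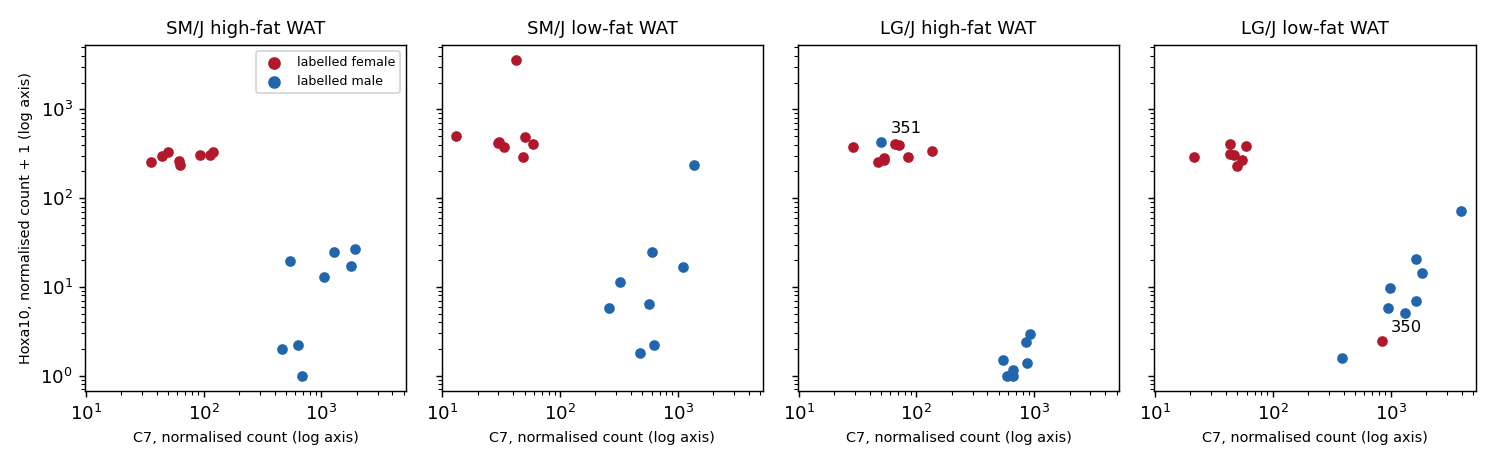
C7 against Hoxa10 in each WAT library, as normalised counts on log axes, with 1 panel per table, 1 point per library and the 2 sexes in separate colours. The libraries labelled 351 (C7 at 50.5, Hoxa10 at 422) and 350 (Hoxa10 at 1.45) lie among the points of the other sex.

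Diet, strain and tissue were not tested across tables, because each table was filtered and scaled separately, and levels per 1000000 normalised counts of a library (CPM) are given side by side. In BAT the lipogenic enzyme Fasn lay at 9281 ± 5327 CPM in SM/J on the high-fat diet and 32759 ± 7376 on the low-fat diet, and in LG/J at 16526 ± 9379 and 22949 ± 10404 (SD, n = 16 in each table). Lep lay in BAT at 718 ± 367 and 259 ± 107 CPM in SM/J and at 183 ± 141 and 142 ± 69.5 in LG/J on the high-fat and low-fat diets. Ucp1 lay in BAT at 4600 ± 736, 4539 ± 874, 6792 ± 1091 and 4894 ± 1481 in SM/J high-fat, SM/J low-fat, LG/J high-fat and LG/J low-fat mice. In WAT it lay at 32.1 ± 28.7, 54 ± 93.7, 31 ± 47.1 and 13.7 ± 17.1. The macrophage gene Adgre1 lay at 369 ± 67.5 CPM in WAT and 34.2 ± 6.01 in BAT of SM/J mice on the high-fat diet.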

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

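The tests of muscle transcripts in SM/J low-fat BAT and of the sex of 2 LG/J WAT libraries were chosen only after the result was seen, as were the age by tissue and sex by diet comparisons, while the marker score covariates for the age genes were added after those genes were seen but before their own result, and the ranges of their ratios after the ratios were seen.

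Between groups, 16 differences of effects passed an interaction test. The age effect in high-fat BAT differed between SM/J and LG/J for Dut (0.56), Tctn1 (0.75) and Gldc (-1.27). It differed between BAT and WAT of SM/J mice on the high-fat diet for Cxcr4 (0.71), Sema3f (-1.20), Gldc (-1.17), Slc4a4 (-0.93), Thbd (-0.84), Epb41l3 (-0.63), Zfp36l2 (-0.63), Hip1r (-0.54), Mark4 (-0.52), Unc119b (-0.45) and Cdv3 (-0.39). The sex effect in SM/J BAT differed between the diets for Mrc2 (-0.77) and Sypl2 (1.36).

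In 6 of 148 tests, each of 1 named gene in 1 group of 4 libraries, 1 library lay far from the other 3. Chance gives about 1 in 20 for independent tests, which these are not, since the genes share libraries. Among 20-week females of SM/J high-fat BAT, Fasn was 487403 in 756 (others 113632 to 171475), Pdpn 120.9 in 292 (others 66.3 to 72.5) and Sctr 137 in 864 (others 123 to 125). Among 20-week males of SM/J high-fat WAT, library 290 had Mki67 at 1207 (others 1589 to 1617) and Tlcd2 at 2237 (others 1660 to 1722). Among 30-week females there, Col1a1 was 17933 in 740 (others 8936 to 10449).

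The first pattern weighed is the 193 age genes of SM/J high-fat BAT. Muscle carried over with the tissue would shrink their changes once the muscle score is a covariate, but the median signed change kept a ratio of 1.00 (0.479 with and without it, 0.96 to 1.04 leaving out 1 library), with 154 genes called, 130 of them shared, which argues against it as the whole cause, while without the libraries with a muscle score above 0, a smaller set, 0 genes were called. With the macrophage score as covariate the ratio was 0.859 (median change 0.411, ratio 0.826 to 0.915), and all 193 genes had the same sign. The sign says little, because the genes were chosen for an age effect in these same libraries. The ratio argues against a change in macrophage share, as this score measures it, as the whole cause, though it may account for a part. Markers in the score moved both ways, so it measures the share only roughly. With this score the calls dropped to 8, 7 of them shared, while the changes shrank and their median SE grew from 0.098 to 0.121. A change of the tissue with age stays open and was not tested separately from other causes that follow age.

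The second pattern is the lower level of all 13 muscle markers at 30 weeks in SM/J low-fat BAT. Within groups the markers moved together from library to library (median pairwise r 0.927 over 78 pairs), as muscle carried over in single libraries could give. An exact permutation of age within sex gave the score difference of -3.49 a two-sided p of 0.00735, which restates the difference that drew attention to the markers and decides nothing on carry-over without regard to age. The 13 markers together made up at most 0.104% of a library there, which does not bound the share of all muscle transcripts. In SM/J high-fat BAT the score difference was -1.80 (exact p = 0.277). Dissection that differed with age and a difference of the tissue itself both stay open, and neither was tested.

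The third pattern is the pair of LG/J WAT libraries whose sex genes go against their label. On a scale from 0 (median female) to 1 (median male), the library labelled high-fat male 351 lay at -0.175 over 76 genes and that labelled low-fat female 350 at 1.02 over 65. A wrong recorded sex of animal 350 is argued against by its BAT library, at -0.468 over 137 genes and outside the males (-0.174 to 1.38), in a table where 2 of 16 libraries lay nearer the other sex, among them the lowest male, while for animal 351 it stays open, at 0.152 over 67 genes among the females (-0.224 to 0.542) in a table where 3 of 16 libraries lay nearer the other sex, although C7 there lay at 104 against 17.7 to 38.7 in females; both were first tested together, which decided nothing (1 of 2 nearer the other sex), then on C7, which was dropped because its choice used both libraries, and the numbers were taken as the animals. A mixture of both sexes is argued against, since 0 of the 2 lay between 0.25 and 0.75. An exchange of these libraries may be the source, since among females the library labelled 351 lay at a diet position of -0.124, nearer low-fat females (0.0459 to 0.451) than high-fat females (0.551 to 1.06), while library 350 lay at 0.411 among males, within both diets' ranges, and no biological explanation was tested.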

How the results depend on the processing

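The marker score covariates, the leaving out of libraries with muscle transcripts or doubtful identity, the fit without a block by animal, and all alternatives of age by tissue, sex by diet and sex in 6 further tables were chosen only after the result was seen.

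With a pseudocount of 0.1, all 24 counts of called genes stayed within 1.5 times, as did 23 of 24 with RLE, 19 of 24 with genes of at least 5 CPM, 13 of 23 in 1 fit to the 64 libraries of a tissue, 10 of 11 with the mesothelial and 6 of 11 with the muscle score, and 8 of 10 without doubtful libraries. Of these, 11 counts were 0 in both fits with the pseudocount, with RLE and at 5 CPM, 8 in the fit to 64 libraries, 6 with the mesothelial score, 4 with the muscle score and 6 without doubtful libraries. Of values for named genes that left out 1 library, 11061 kept their side of the threshold, 1046 lost it, 213 gained it and 0 reversed. With an estimated correlation 2 of 94 camera calls of the planned comparisons were left, and 0 of 62 of those added. The cause was not tested for any change of a count below, except that fits of 1 sex or without some libraries hold fewer samples.

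Age in SM/J high-fat BAT (193) fell to 3 in females, 1 in males, 8 with the macrophage score, 9 with macrophage and muscle scores, and 0 in limma without libraries with a muscle score above 0 (1690 at an unadjusted p under 0.05). Age in SM/J high-fat WAT (5) was 3 at 5 CPM, 3 over 64 libraries, 0 in females and 1 in males. Over 64 libraries, age gave 26 in SM/J low-fat BAT, 1 in LG/J high-fat BAT and 21 in SM/J low-fat WAT (each 0), age by strain in BAT 0 (3), sex 28 in SM/J high-fat BAT (3), 262 in SM/J high-fat WAT (961), 1076 in LG/J low-fat BAT (261) and 3162 in SM/J low-fat WAT (1846), and sex by diet 1 (2). At 5 CPM, age by strain in BAT gave 1, sex in SM/J high-fat BAT 0, sex by diet 1 and age by tissue 59 (11), which was 20 with RLE and 4 without the block. With the muscle score, age in SM/J low-fat BAT gave 4, sex in SM/J high-fat BAT 1, sex by diet 0, sex in SM/J low-fat BAT 369 (1359) and in LG/J low-fat BAT 61, and the sex effect on Pvalb in SM/J low-fat BAT reversed from -3.92 to 0.12. Sex in LG/J high-fat WAT (1478) was 32 with the mesothelial score and 3562 without library 351, and sex in SM/J low-fat WAT was 2860 without library 699.

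Leaving out 1 library, age in SM/J high-fat BAT gave 64 to 609 genes, with 121 without 864, 64 without 290 or 704, 609 without 734, 83, 122 and 119 without 729, 740 and 786, and 85, 74 and 95 without 653, 655 and 656. Age in SM/J low-fat BAT gave 0 to 258 (699 1, 336 49, 542 5, 650 258), and age in SM/J high-fat WAT 1 to 9 (864 9, 862 3, 700 2, and 1 without 756, 290, 703, 704, 734, 646, 740, 786, 653, 655 or 656). Age by diet in BAT gave 0 to 1 (1 without 862, 734 or 655) and in WAT 0 to 1 (1 without 542 or 662), and age by strain in WAT 0 to 1 (1 without 864). Age by strain in BAT gave 0 to 22 (22 without 734, 6 without 276, 5 without 703, 1 without 623 or 688, 0 without 22 others). Sex in SM/J high-fat BAT gave 1 to 305 (700 305, 734 293, 646 7, and 1 without 862, 864, 729, 740, 653 or 656), and sex by age in BAT 0 to 4 (734 4, 700 2, 740 1). Age by tissue gave 1 to 264 (862 264, 734 88, 700 24, 653 20, 292 6, 290 5, 655 4, 656 2, 756 1), and sex by diet 0 to 30 (761 30, 336 15, 655 14, 699 13, 627 12, 490 7, 1 without 703, 740 or 552, 0 without 18 others). Sex in SM/J high-fat WAT gave 752 to 1107, and in SM/J low-fat BAT 532 to 1836 (724 598, 730 532, 336 891, 542 839, 489 749, 552 837). In LG/J high-fat BAT sex gave 176 to 700 (520 198, 709 270, 344 176, 351 700, 403 257, 510 246, 688 207, 537 673, 619 203, 625 183) and in LG/J low-fat BAT 72 to 811 (350 85, 535 76, 612 172, 319 811, 481 72, 482 100, 483 140). In SM/J low-fat WAT it gave 1323 to 2860 (699 2860), in LG/J high-fat WAT 627 to 3562 (344 629, 351 3562, 403 664, 281 856, 509 772, 510 777, 533 627, 537 3372, 619 691, 625 774) and in LG/J low-fat WAT 305 to 693 (349 324, 587 360, 612 305, 339 359, 524 309, 482 356). The other counts stayed at 0 to 0.

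The alternative test with DESeq2 was not run, since the values are not counts. A filter at a mean of 1 against none removes no gene and says nothing. The tests of diet, strain and tissue across tables were not run, nor was the muscle score for age by strain in BAT, because LG/J high-fat BAT held too few muscle markers. The depth in reads is unknown.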

Other observations

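The tests of splits for age by tissue, sex by diet and sex in 6 further tables belong to comparisons chosen only after the result was seen, and the other splits were planned.

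Other gene groups of the SM/J high-fat mice with a camera call had no member past the threshold over all genes. In the difference of age effects between males and females in BAT, 13 of 13 muscle markers were positive with a median of 4.86 (adjusted p = 0.73 with an estimated correlation). In WAT the endothelial markers had positive differences in 12 of 12 cases with a median of 0.29 (adjusted p = 0.814 with an estimated correlation). On the high-fat diet thermogenic genes in BAT were lower in males in 15 of 19 cases, with a median of -0.17 (adjusted p = 0.484 with an estimated correlation), and fatty acid synthesis genes in 15 of 15 (adjusted p = 0.642 with an estimated correlation).

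In SM/J low-fat WAT further groups differed by sex. Unfolded protein response genes had 5 members higher in males over all genes and 11 adjusted over the list alone (adjusted p = 0.403 with an estimated correlation). Endothelial markers had 5 lower, and 7 adjusted over the list alone, with a median of -0.33 (adjusted p = 0.579 with an estimated correlation). In LG/J low-fat WAT, B cell markers were higher in males in 6 of 6 cases with a median of 0.72 (adjusted p = 0.577 with an estimated correlation).

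For the 193 age genes of SM/J high-fat BAT all drawn splits stayed below the real count (1 of 100, highest other 93). This argues against chance but does not exclude it, since 1 of 100 is the lowest value these splits can give. Leaving out 1 library also gave 64 to 609 genes, at the lowest fewer than the 93 of that split. For sex all drawn splits also stayed below the real count in SM/J high-fat WAT (961, 1 of 100, highest other 401), SM/J low-fat BAT (1359, 1 of 100, 381), LG/J high-fat BAT (407, 1 of 100, 111), LG/J low-fat BAT (261, 1 of 100, 5), SM/J low-fat WAT (1846, 1 of 100, 468) and LG/J low-fat WAT (572, 1 of 100, 0), which argues against chance there. The count for age by tissue was reached by no drawn split either (11, 1 of 100, highest other 1). That comparison was added after the data were seen, and leaving out 1 animal gave 1 to 264 genes, so chance is not taken as excluded for it. Fewer than 5 of 100 splits also reached the count for sex in LG/J high-fat WAT (1478, 2 of 100, 2927) and age in SM/J high-fat WAT (5, 4 of 100, 2216). The same held for sex by diet in SM/J BAT (2, 4 of 100, 965). In these 3 another split called more genes than the real one, so chance is not taken as excluded for them. For sex by diet the shuffle also broke up the sex effect within each diet, so it does not test the difference alone. In the last 2 another split called many times more, which points to a structure of the samples, and its source was not tested. Chance was not excluded for age by strain in high-fat BAT (3, 6 of 100, highest other 155) or sex in SM/J high-fat BAT (3, 5 of 100, highest other 1345), where the splits also point to such a structure.

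Where 0 genes were called, a count of 0 is matched by all 100 of 100 splits whatever the data, so these splits say nothing on chance. The highest other splits were 42 for age in SM/J low-fat BAT, 16 and 267 in LG/J high-fat and low-fat BAT, 0 in SM/J low-fat WAT, and 8 and 1256 in LG/J high-fat and low-fat WAT. They were 625 and 515 for age by diet in BAT and WAT, 2480 for age by strain in WAT, and 284 and 1164 for sex by age in BAT and WAT, which points to a structure of the samples there.

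In SM/J high-fat BAT, over 18 sex genes, male 700 of 30 weeks lay at 0.164 and male 734 of 20 weeks at 0.452 on the scale from females to males, while their WAT libraries lay at 1.03 and 1.08. In SM/J low-fat WAT the 20-week female 699 had Hoxa10 at 3549.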
